A study of Mus musculus with 9 samples.

How the data were processed

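Primary mesangial cells, the contractile support cells of the glomerular tuft, were isolated from kidneys of C57BL/6 mice aged 8 to 10 weeks, per the labels' protocols. They were grown with 20% foetal calf serum and 1% ITS, a culture supplement. Per the labels, 3 arrays came from cells given lipofectamine, a cationic lipid transfection reagent, 3 from cells given non-CpG DNA and 3 from cells given 3P-RNA, all at 6 h. Whether the ligands were delivered with the same lipid is not stated in the labels. Biotinylated cRNA was made from 6 µg of total RNA and hybridised to Affymetrix MOE430_2 arrays, on which a set of short probes (a probe set) reads each transcript.

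The deposited table holds 1 expression value per probe set and array, as an intensity on a linear scale. The submitters' processing notes name RMA, a method that corrects background, normalizes arrays to a common distribution and summarises the probes of a set. Its version, background model and any scaling afterwards are not given in the sources used here. The values run from 2.08 to 7294.8 with a median of 8.62. Sorted intensities of the 9 arrays differ by at most 1.09 times at any rank, so the arrays had been brought to nearly the same distribution before deposit. A global rise or fall of all transcripts would therefore not be visible in these distributions, and log2 fold changes are relative to the other genes of the same array. Of all log2 values, 48.3% lie under 3, a range in which differences in probe brightness say little about transcript level. No detection calls were used here, so a probe set in that range has a value and no statement of absence. The table held 0 columns of other samples, and array medians ran from 8.41 to 8.75.

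The 45101 probe sets were named through the platform's annotation table, with symbols looked up by gene identifier in a RefSeq gene table of assembly GRCm38.p6, used for names alone. Of them, 34945 carried 1 gene symbol, 932 carried several, 9160 were unnamed here and 64 were Affymetrix controls. Identifiers of 34741 of the 34945 were found in the RefSeq table, and 0 symbols changed. Log2 was taken, and each gene was represented by its probe set with the highest mean over the 9 arrays, which gave 18193 genes. Among them 9010 genes had further probe sets. No filter on low values was applied. Among called genes with several probe sets, a further probe set was called in the opposite direction for 103 of 3269 genes after non-CpG DNA, 7 of 1519 after 3P-RNA and 2 of 851 between the ligands.

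Groups were compared with the linear model and empirical Bayes test of limma 3.58.1 in R 4.3.3, fitted on all 9 arrays with 1 coefficient per group. This left 6 residual degrees of freedom per gene, to which the prior added 4.59. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over the genes tested), and a second count added a change of at least 2-fold. All adjusted p of single genes below are from limma. Standard errors are those of the moderated fit and SDs are over the 3 arrays of a group. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, which asks whether a list moved more than the other genes. Camera with an estimated correlation was run beside it, and so was fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. P-values of the lists are adjusted over the 23 lists of a comparison. The lists hold 446 genes, of which 391 were measured. Members with no probe set of their own under a matching symbol were not analysed here. RIG-I is among them, because its list carries a newer symbol than the annotation, which names it Ddx58.

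Groups, tests, the 23 lists and the rule for naming genes were fixed before the data were examined. The rule took the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between groups. It added up to 4 called members of each list with the largest changes, or the 2 brightest members where 0 were called, and Ifnb1, Ifit1, Cxcl10, Ccl5, Il6, Irf7 and Tnf whatever their test. Genes named outside the rule are said to be so. Alternatives were other normalizations, other choices of probe set, a filter on dim genes, other variance models, array weights, stricter thresholds, the replicate number as a block, and leaving out each array. Setting every value under the overall median to that median was added after the data were seen.

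On simulated data built from the 3P-RNA comparison over 18193 genes, the same steps recovered 22% of genes changed by 0.3 on the log2 scale, 86% at 0.5, and 100% at 1 and at 2. They made 9 false calls, 5.52% of all calls, and 0 calls in a comparison with no change. A list of 20 genes shifted by 0.5 was recovered, and 0 of 50 unshifted lists were called. The simulated genes were independent of each other, whereas the estimated correlation was 0.426 among immediate-early genes and 0.316 among interferon-inducible GTPases. How often lists of correlated genes are called falsely was therefore not shown. The number of arrays limits the precision, with a median standard error of 0.08 on the log2 scale. The labels do not say that replicates came from separate cultures or animals, so p-values measure the spread between these arrays, which may be technical. Figures were drawn with matplotlib.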

Results

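The data are expression profiles of mouse primary mesangial cells at 6 h after non-CpG DNA (DNA without CpG motifs), 3P-RNA (RNA that carries a triphosphate at its 5′ end) or lipofectamine alone, with 3 arrays per group and 18193 genes tested. Log2 values of arrays of the same group correlated across probe sets at r = 0.995 to 0.998, and those of different groups at r = 0.988 to 0.996. The first principal component of the genes held 61% of the variance. On it the controls lay at -26.6 to -23.4, the 3P-RNA arrays at -1.26 to 4.04 and the non-CpG DNA arrays at 20.96 to 28.49. The second, with 11.3%, set the 3P-RNA arrays (-13.3 to -11.0) apart from all others (3.71 to 10.1). As a sign of RNA quality, the log2 difference between 3′ and 5′ control probe sets of Gapdh and beta-actin averaged 0.35 ± 0.10 in controls, 0.33 ± 0.07 after non-CpG DNA and 0.28 ± 0.01 after 3P-RNA (SD, n = 3). Group means of spiked-in hybridisation controls lay apart by about the spread between arrays, a difference that was not tested. The probe sets of BioB and BioC read 0.21 to 0.31 higher on average on the non-CpG DNA arrays than on the controls and those of BioD 0.14 to 0.18 higher, while the 3P-RNA arrays differed from controls by -0.05 to 0.11. Averaged over its probe sets, BioB read 6.74 ± 0.23 in controls, 6.99 ± 0.19 after non-CpG DNA and 6.77 ± 0.37 after 3P-RNA (SD, n = 3), with arrays of all groups overlapping.

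The first comparison asked what non-CpG DNA changed against lipofectamine alone. Several genes of the antiviral interferon response were among the largest rises. Ifit1, which binds foreign RNA caps, went from a log2 intensity of 2.07 ± 0.07 to 9.70 ± 0.20 (SD, n = 3), and the chemokine Cxcl10 from 3.84 ± 0.20 to 9.80 ± 0.14, a 62.0-fold rise. Usp18, a negative regulator of the interferon receptor, rose by 5.71 ± 0.12 on the log2 scale (SE), and the cytokine Il6 by 4.66 ± 0.23. Most cholesterol, immediate-early and p53 target genes rose as well, while most cell cycle genes and many matrix genes fell. As lists, the immediate-early, cell cycle and matrix genes lost their call with an estimated correlation (adjusted p = 0.0543, 0.139 and 0.4). In all, 5289 genes (29.1%) were called, 2074 higher and 3215 lower, of which 180 and 189 changed at least 2-fold, and the median size of a called change was 0.42, against the 0.21 to 0.31 by which BioB and BioC differed.

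Of 30 measured interferon-stimulated antiviral effectors, 21 rose, 0 fell and 9 were not called, with 24 higher when adjusted over the list alone. Their median change was 0.88 (camera adjusted p = 9.43e-18, and 0.0351 with an estimated correlation). Besides Ifit1 and Usp18, Rtp4 rose by 4.37 ± 0.15 and Rsad2, which makes a chain-terminating nucleotide, by 3.54 ± 0.18. The control level of Ifit1, Usp18 and Il6 lay under the overall median of 3.11, so their folds depend on how low values are read. With low values set to that median, the folds were 96.7 in place of 198.6 for Ifit1, 29.5 in place of 52.5 for Usp18 and 12.1 in place of 25.2 for Il6.

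Interferon-inducible GTPases, which act on intracellular pathogens, rose in 8 of 9 measured members, also when adjusted over the list alone (median 1.68, camera adjusted p = 6.07e-10, and 0.0453 with an estimated correlation). Iigp1 rose by 3.39 ± 0.25, or 2.22 with low values set to the overall median, Gbp3 by 3.26 ± 0.09, Igtp by 2.97 ± 0.09 and Irgm2 by 2.91 ± 0.11. Among 18 genes of interferon receptor signalling, 8 rose and 2 fell (camera adjusted p = 0.00127, and 0.0453 with an estimated correlation; 8 and 3 when adjusted over the list alone). The transcription factor Irf7 rose by 2.53 ± 0.21, Irf9 by 2.05 ± 0.09 and Stat2 by 1.79 ± 0.15. Irf5 rose by 0.90 ± 0.28, a call that was lost without any 1 control array. The 2 that fell were Jak2 (-0.28) and Ifnar1 (-0.20), named after their values were seen. Nucleic acid sensors and adaptors split into 8 higher and 4 lower of 20, the same counts as when adjusted over the list alone, and their camera call (adjusted p = 0.032) was lost at adjusted p = 0.0963 with an estimated correlation, without dim genes and with low values at the median. Ifih1, a sensor of double-stranded RNA, rose by 2.81 ± 0.12 and the ubiquitin ligase Trim25 by 1.42 ± 0.10. The members that fell were Ikbke (-0.54), Tlr2 (-0.50), Unc93b1 (-0.35) and Mavs (-0.29), named after their values were seen. The calls of Ifi204 and Dhx58, whose group means lay under the overall median, ended when low values were set to it. Genes of the MHC class I list rose in 7 and fell in 1 of 15 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00729, lost at adjusted p = 0.219 with an estimated correlation). The peptide transporter Tap1 rose by 1.09 ± 0.10. Cd274 rose by 1.33 ± 0.14 and is counted in the list, although it encodes no MHC class I or antigen-processing protein.

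The interferon genes themselves did not pass the test. All 8 measured interferon genes are of type I, and those of type III were not analysed here. Of the 8 limma called 0, with 0 at an unadjusted p under 0.05, and the list was not shifted (median 0.07, camera adjusted p = 0.456). Ifnb1 read 2.64 ± 0.03 in controls and 2.60 ± 0.03 after non-CpG DNA (limma adjusted p = 0.75, n = 3), under the overall median in both groups. Ifna1 (limma adjusted p = 0.146) and Ifna9 (limma adjusted p = 0.958) were the brightest of the list. Tnf read 2.61 ± 0.17 and 2.76 ± 0.01 (limma adjusted p = 0.302, n = 3).

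Inflammatory cytokines and NF-kappaB target genes rose in 19 and fell in 2 of 34 (20 and 2 adjusted over the list alone), with a median of 0.46 (camera adjusted p = 6.07e-10, and 0.0351 with an estimated correlation). Lif rose by 2.79 ± 0.13, Ptgs2, the inducible prostaglandin synthase, by 2.39 ± 0.09 and Csf2 by 1.78 ± 0.10, or 1.23 with low values set to the overall median. Chemokines rose in 11 and fell in 1 of 27, the same counts adjusted over the list alone (median 0.15, camera adjusted p = 8.7e-05, and 0.0351 with an estimated correlation). Ccl5 rose 20.0-fold, Cxcl1 5.08-fold and Ccl2, which attracts monocytes, 4.41-fold. Named after their values were seen, the members that fell were the chemokine Cxcl12, by 1.81 ± 0.12, and the cytokine genes Il18 (-0.64) and Il1rn (-0.33). Immediate-early genes rose in 15 of 17 (median 1.05, also 15 adjusted over the list alone), among them Nr4a1 by 2.58 ± 0.21, Fos by 2.27 ± 0.14, Fosl1 by 2.21 ± 0.10 and Nr4a2 by 2.15 ± 0.14. The camera adjusted p of that list was 1.15e-14, and 0.0543 with an estimated correlation, at which the call was lost.

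Cholesterol synthesis and uptake genes rose in 12 of 17 and fell in 0 (13 and 0 adjusted over the list alone; median 0.68, camera adjusted p = 1.24e-09, and 0.0453 with an estimated correlation). Insig1, a feedback regulator of sterol synthesis, rose by 1.55 ± 0.14, Idi1 by 1.30 ± 0.07, Msmo1 by 1.20 ± 0.08 and Cyp51 by 1.04 ± 0.08. Of 14 p53 target genes 11 rose and 1 fell (12 and 1 adjusted over the list alone; median 0.70, camera adjusted p = 2.47e-08, and 0.0351 with an estimated correlation). Btg2 rose by 2.16 ± 0.15, Mdm2, the ubiquitin ligase of p53, by 2.08 ± 0.07 and the cell cycle inhibitor Cdkn1a by 1.67 ± 0.09, while Sesn1 fell by 1.76 ± 0.11. Cell death genes rose in 10 and fell in 3 of 22, also adjusted over the list alone (camera adjusted p = 0.00144, and 0.048 with an estimated correlation), with Xaf1 up by 2.91 ± 0.17, Pmaip1 by 2.08 ± 0.08, Casp4 by 1.40 ± 0.10 and Fas by 1.18 ± 0.06. In the unfolded protein and integrated stress response list 8 of 17 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0428, lost at adjusted p = 0.4 with an estimated correlation, at 0.0634 with the replicate number as a block, and also with array weights, without probe sets that may read several transcripts, and without control replicate 1 or 2 or non-CpG DNA replicate 2). Atf3, a stress-induced transcription factor, rose by 3.51 ± 0.16 and Ddit3 by 1.00 ± 0.08, while Chac1 fell by 0.73 ± 0.08.

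Cell cycle genes fell in 17 and rose in 1 of 24 (18 and 2 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 1.37e-06, lost at adjusted p = 0.139 with an estimated correlation). Bub1b and Ccnb2 each fell 1.69-fold, Mki67 1.55-fold and Bub1 1.54-fold, and the 1 that rose was the cyclin Ccnd1, by 0.35 ± 0.07, named after its value was seen. Extracellular matrix genes fell in 15 and rose in 4 of 29 (16 and 4 adjusted over the list alone; median -0.23, camera adjusted p = 0.0303, lost at adjusted p = 0.4 with an estimated correlation, without dim genes, and without control replicate 3 or non-CpG DNA replicate 1). The hyaluronan synthase Has2 rose by 1.45 ± 0.08. Dcn fell by 0.86 ± 0.18. Mmp13 rose by 1.71 ± 0.21 from a level under the overall median, and its call ended when low values were set to that median.

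The other large rises were those of the growth factor Ereg (3.91 ± 0.16) and the natriuretic peptide Nppc (3.54 ± 0.11). The largest falls were in Dhrs3, a retinal reductase, by 2.82 ± 0.19, Rgs4, a regulator of G protein signalling, by 2.41 ± 0.07, Rassf2 by 2.39 ± 0.14, Dbp, a clock output transcription factor, by 2.30 ± 0.17, Lrrc17 by 2.21 ± 0.13, C1qtnf1 by 2.12 ± 0.16, Kif26b by 2.08 ± 0.11, Pde5a by 1.94 ± 0.11 and Camk1g by 1.88 ± 0.20. Bmf fell by 2.51 ± 0.09 on a probe set that may read other transcripts too, and the call was lost without probe sets of that kind. With low values set to the overall median, the change was -2.05 for Rgs4, -2.29 for Rassf2 and -2.18 for Bmf.

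Of 16 mesangial and contractile markers 1 rose and 4 fell (median -0.03, camera adjusted p = 0.423). The growth factor receptors Pdgfra and Pdgfrb fell by 1.04 ± 0.07 and 0.87 ± 0.10, and Edn1 rose by 0.85 ± 0.08. Itga8 (-0.30 ± 0.10) lay under the overall median in both groups, and its call was lost in 13 alternatives, among them the replicate number as a block, array weights and leaving out control replicate 1 or 3 or any 1 non-CpG DNA array. Markers of other cells were not shifted as lists by camera, with medians of 0.03 for macrophages and leukocytes (adjusted p = 0.705), 0.07 for lymphocytes (adjusted p = 0.244), 0.09 for endothelium (adjusted p = 0.131), -0.03 for podocytes (adjusted p = 0.705) and -0.02 for tubular epithelium (adjusted p = 0.705). Fry, which does not compare a list with other genes, called the endothelial (adjusted p = 0.00189) and lymphocyte (adjusted p = 0.0478) lists upward and the mesangial (adjusted p = 0.00249), tubular (adjusted p = 0.00583) and podocyte (adjusted p = 0.0315) lists downward. Of the 14 macrophage and leukocyte markers 4 exceeded the overall median in any group. Lyz2, named after its value was seen, read 2.90, 2.84 and 2.94 in control, non-CpG DNA and 3P-RNA arrays. Csf1r fell by 1.36 ± 0.21, and the calls of Cd68 (0.46 ± 0.13), Mpeg1 (0.45 ± 0.07) and Coro1a (-0.36 ± 0.11) were in genes under that median, and ended with low values set to it. Those of Cd68 and Coro1a were lost also without control replicate 1 or non-CpG DNA replicate 1 or 3, and that of Coro1a with the replicate number as a block, array weights and other choices of probe set. Synpo, listed with podocytes, fell by 1.18 ± 0.08, Flt1, listed with endothelium, rose by 0.91 ± 0.19, and Cubn, listed with tubules, fell by 1.12 ± 0.14. MHC class II genes (median 0.02, adjusted p = 0.888, 0 of 9 called by limma and 1 at an unadjusted p under 0.05) and reference genes (median 0.00, adjusted p = 0.888) were not shifted, although 4 of 9 reference genes were called, Hprt (0.43 ± 0.08) and Ywhaz (0.30 ± 0.06) higher and Gusb (-0.39 ± 0.06) and Sdha (-0.34 ± 0.06) lower. The call of Gusb was lost with the mean of its probe sets and that of Ywhaz with another choice of probe set. The macrophage and leukocyte list had a mean of -0.04, against the sign of its median and of its test.

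**Figure D1:**
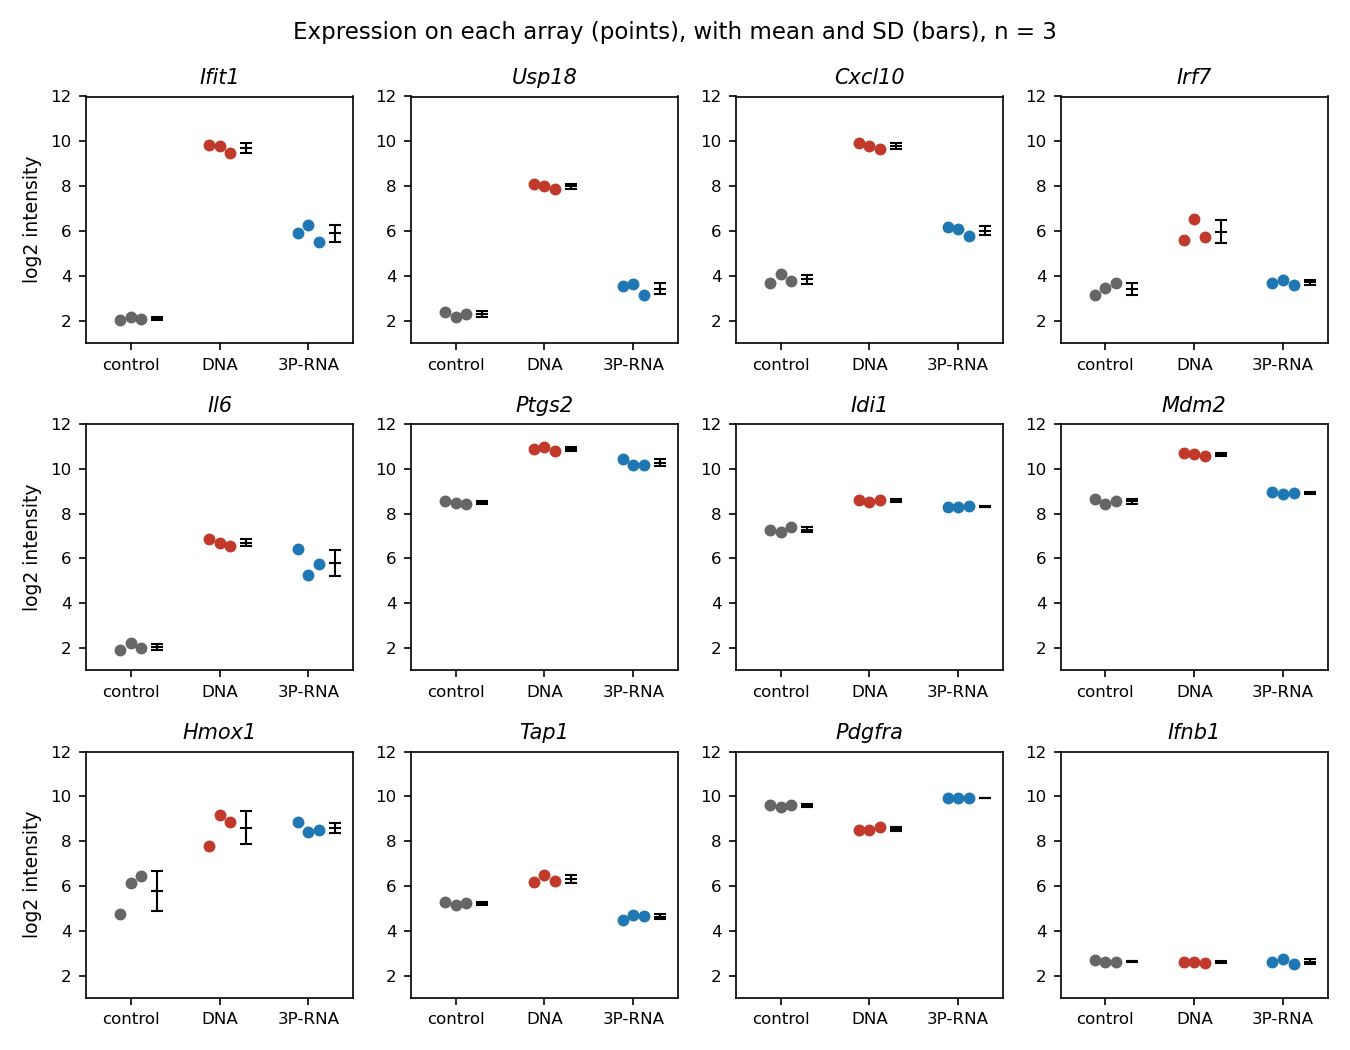
Log2 intensity of 12 genes on each of the 9 arrays (points), with mean and SD over 3 arrays (bars), for lipofectamine control, non-CpG DNA and 3P-RNA. Ifit1 lies at 2.07 in controls, 5.90 after 3P-RNA and 9.70 after non-CpG DNA, whereas Ifnb1 lies between 2.60 and 2.64 in all 3 groups.

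The second comparison asked what 3P-RNA changed against lipofectamine alone. The lists of inflammatory, chemokine, cholesterol and immediate-early genes shifted up. Members called higher were 15 of 34, 8 of 27, 13 of 17 and 10 of 17, in that order. Of the 30 interferon-stimulated effectors 6 were called higher, and the lists were not tested against each other. As lists, the immediate-early genes and the interferon-stimulated effectors lost their call with an estimated correlation (adjusted p = 0.21 and 0.458). Il6 went from 2.05 ± 0.15 to 5.80 ± 0.59 (SD, n = 3), Ccl5 rose 4.65-fold and Cxcl10 4.47-fold. Ifit1 rose by 3.83 ± 0.16 on the log2 scale (SE), whereas Irf7 moved by 0.27 ± 0.21 and was not called (limma adjusted p = 0.484). With low values set to the overall median, the rise was 2.79 for Ifit1 and 2.69, in place of 3.75, for Il6. In all, 2465 genes (13.5%) were called, 841 higher and 1624 lower, of which 58 and 31 changed at least 2-fold.

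Cholesterol genes rose in 13 of 17 and fell in 0 (14 and 0 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 1.48e-16, and 0.0255 with an estimated correlation). Insig1 rose by 1.17 ± 0.14, Idi1 by 1.02 ± 0.07, Cyp51 by 1.01 ± 0.08 and the sterol carrier Stard4 by 0.99 ± 0.10. Inflammatory and NF-kappaB target genes rose in 15 and fell in 1 of 34 (17 and 1 adjusted over the list alone; median 0.29, camera adjusted p = 1.47e-12, and 0.0203 with an estimated correlation), with Lif up by 2.12 ± 0.13, Ptgs2 by 1.77 ± 0.09 and Il1rn, the interleukin-1 receptor antagonist, by 0.92 ± 0.08. Chemokines rose in 8 and fell in 1 of 27, also adjusted over the list alone (median 0.14, camera adjusted p = 4.2e-07, and 0.0203 with an estimated correlation). Ccl2 rose 3.09-fold and Cxcl1 2.97-fold. Immediate-early genes rose in 10 of 17, also adjusted over the list alone (median 0.49, camera adjusted p = 2.75e-11, lost at adjusted p = 0.21 with an estimated correlation). Nr4a2 rose by 2.23 ± 0.14, Nr4a1 by 2.15 ± 0.21, Fos by 1.26 ± 0.14 and Fosl1 by 1.13 ± 0.10.

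Of the 30 interferon-stimulated effectors 6 rose, 3 fell and 21 were not called, also adjusted over the list alone. Their median was 0.03 and the camera adjusted p 0.0447, a call lost at adjusted p = 0.458 with an estimated correlation, at 0.133 without control replicate 1, at 0.16 without 3P-RNA replicate 2, at 0.108 with array weights and at 0.196 with low values at the median. Fry gave an adjusted p of 0.0599. Rtp4 rose by 1.30 ± 0.15 and Rsad2 by 0.76 ± 0.18, the latter call lost without control replicate 1 or 3, or without 3P-RNA replicate 1 or 2. Usp18 rose by 1.15 ± 0.12, and lost its call with low values set to the median (limma adjusted p = 0.202). The 3 that fell, named after their values were seen, were Parp12 by 0.54, Isg20 by 0.42 and Samhd1 by 0.19. Among 9 interferon-inducible GTPases Gbp3 rose by 0.33 ± 0.09 and Irgm1 fell by 0.44 ± 0.07, also adjusted over the list alone (median -0.02 and mean 0.03, with camera's direction upward, adjusted p = 0.684). The call of Gbp3, whose means in these groups lay under the overall median, was lost without any 1 control array and with low values set to that median (0.06, limma adjusted p = 0.758). Interferon receptor signalling had 3 higher and 0 lower of 18, also adjusted over the list alone (median 0.08, camera adjusted p = 0.116), with Socs3, a feedback inhibitor of cytokine receptors, up by 1.05 ± 0.09 and Irf9 by 0.48 ± 0.09. Sensors had 2 higher and 3 lower of 20 (3 and 3 adjusted over the list alone; median 0.03, camera adjusted p = 0.682), with Unc93b1 down by 0.40 ± 0.07, Ikbke by 0.38 ± 0.08 and Tlr2 by 0.35 ± 0.07. Tlr9, of the sensor list too, rose by 0.24, a call lost in 10 alternatives, among them leaving out any 1 control or 3P-RNA array. MHC class I genes had 0 higher and 2 lower of 15, also adjusted over the list alone (median -0.05, camera adjusted p = 0.413). Tap1 fell by 0.59 ± 0.10, a call lost with the mean of its probe sets, and H2-M3 by 0.26 ± 0.08, a call lost without any 1 control array. Ifnb1 read 2.62 ± 0.11 (limma adjusted p = 0.957, n = 3) and Tnf 2.63 ± 0.15 (limma adjusted p = 0.942, n = 3). Of the 8 interferon genes limma called 0, with 0 at an unadjusted p under 0.05 (median -0.01 and mean 0.01, with camera's direction upward, adjusted p = 0.697).

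Cell cycle genes fell in 6 and rose in 1 of 24 (11 and 1 adjusted over the list alone; median -0.19, camera adjusted p = 0.0028, lost at adjusted p = 0.458 with an estimated correlation), with Bub1b down by 0.36 ± 0.08 and Plk1 by 0.38 ± 0.10, the call of Plk1 being lost without any 1 array of either group. Stress response genes rose in 4 and fell in 1 of 17 (6 and 1 adjusted over the list alone; median 0.11, camera adjusted p = 0.00273, lost at adjusted p = 0.443 with an estimated correlation), with Atf3 up by 1.62 ± 0.16, Ddit3 by 0.51 ± 0.08 and Ddit4 by 0.45 ± 0.07. The p53 targets had 2 higher and 1 lower of 14 (4 and 1 adjusted over the list alone; median 0.04, camera adjusted p = 0.206). Btg2 rose by 1.01 ± 0.15, Mdm2 by 0.36 ± 0.07, and Sesn1 fell by 0.90 ± 0.11. Cell death genes had 3 higher and 1 lower of 22 (3 and 2 adjusted over the list alone; median 0.03, camera adjusted p = 0.271), with Casp4 up by 1.03 ± 0.10. Matrix genes had 4 higher and 4 lower of 29 (4 and 5 adjusted over the list alone; median -0.07 and mean 0.07, with camera's direction downward, adjusted p = 0.697), with Has2 up by 1.27 ± 0.08, Mmp3 by 0.89 ± 0.16 and Mmp2 down by 0.35 ± 0.07. Mmp13 rose by 2.02 ± 0.21, or 0.57 with low values set to the median.

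Among single genes, Dio2, which activates thyroid hormone, rose by 2.90 ± 0.11, Nppc by 2.60 ± 0.11, Ereg by 2.41 ± 0.16 and Tcim by 2.16 ± 0.13. With low values set to the overall median, the rise of Dio2 was 2.52. The haem-degrading enzyme Hmox1 rose by 2.82 ± 0.43, from 4.74, 6.12 and 6.46 on the 3 control arrays to 8.59 ± 0.24 (SD, n = 3). The largest falls were in Pik3ip1 by 1.45 ± 0.11, Dbp by 1.42 ± 0.17, Rgcc by 1.42 ± 0.16, Rassf2 by 1.38 ± 0.14, Htra3 by 1.32 ± 0.24, Cdsn by 1.26 ± 0.19, Hdac11 by 1.25 ± 0.16, Usp11 by 1.21 ± 0.15, Angpt4 by 1.20 ± 0.20 and C1qtnf1 by 1.19 ± 0.16. The mesangial list was not shifted (median -0.06, camera adjusted p = 0.682), with Pdgfra up by 0.32 ± 0.07 and Pdgfrb down by 0.51 ± 0.10. List medians and camera adjusted p were -0.01 and 0.821 for macrophages and leukocytes, 0.06 and 0.334 for lymphocytes, 0.04 and 0.238 for endothelium, -0.04 and 0.697 for podocytes, -0.06 and 0.697 for tubular epithelium, -0.06 and 0.296 for MHC class II, and 0.04 and 0.525 for reference genes. Among lists that camera did not call, fry called the tubular list downward (adjusted p = 0.0193) and interferon receptor signalling upward (adjusted p = 0.0177). Camera's direction for the macrophage list was upward, against its median and its mean of -0.03. Limma called 0 genes in the lymphocyte, endothelial, MHC class II and reference lists, and 0, 1, 2 and 3 passed an unadjusted p under 0.05. Csf1r fell by 0.73 ± 0.21, a call lost without any 1 of the 3P-RNA arrays, Synpo by 0.47 ± 0.08, and Cubn by 0.66 ± 0.14, a call lost without 3P-RNA replicate 1.

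The counts of this comparison depended on single 3P-RNA arrays. Without 3P-RNA replicate 1 there were 431 genes higher and 745 lower, without replicate 3 there were 548 higher, and without control replicate 3 there were 1017 lower.

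The changes after the ligands overlapped. Of the 841 genes higher after 3P-RNA, 752 (89.4%) were also higher after non-CpG DNA, against 95.9 for independent lists. Of the 1624 lower, 1450 (89.3%) were also lower, against 287. Without 3P-RNA replicate 1 the counts in both were 399 and 689, without 3P-RNA replicate 3 488 were higher, and without control replicate 3 925 were lower. Another 13 genes were higher after non-CpG DNA and lower after 3P-RNA, among them Tap1, and 5 went the other way. Named after their values were seen, the 5 were Il1rn, Pdgfra, Ptgfr, Nrn1 and Vcan, and the 13 included Irgm1, Parp12 and Ddx58, a sensor of triphosphate RNA that its list holds under another symbol and so did not count (0.61 after non-CpG DNA and -0.34 after 3P-RNA). Il6, Lif, Ptgs2, Ccl2, Nppc, Ereg, Insig1 and Idi1 rose after both, and Dbp, Rassf2, C1qtnf1 and Sesn1 fell after both. The comparisons share the control arrays. A simulation of all 9 arrays with no changed gene gave 0 such genes on average. With nothing changed hardly any gene is called, so this count cannot show how much overlap shared controls add. Log2 fold changes correlated across genes, which are not independent replicates, at r = 0.81, against 0.50 in the simulation, with a covariance of 0.0685 against 0.00446. Fold changes had the same sign in 77.5% of genes against 66.7% in the simulation. The excess over independent lists is not called a shared effect.

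**Figure D2:**
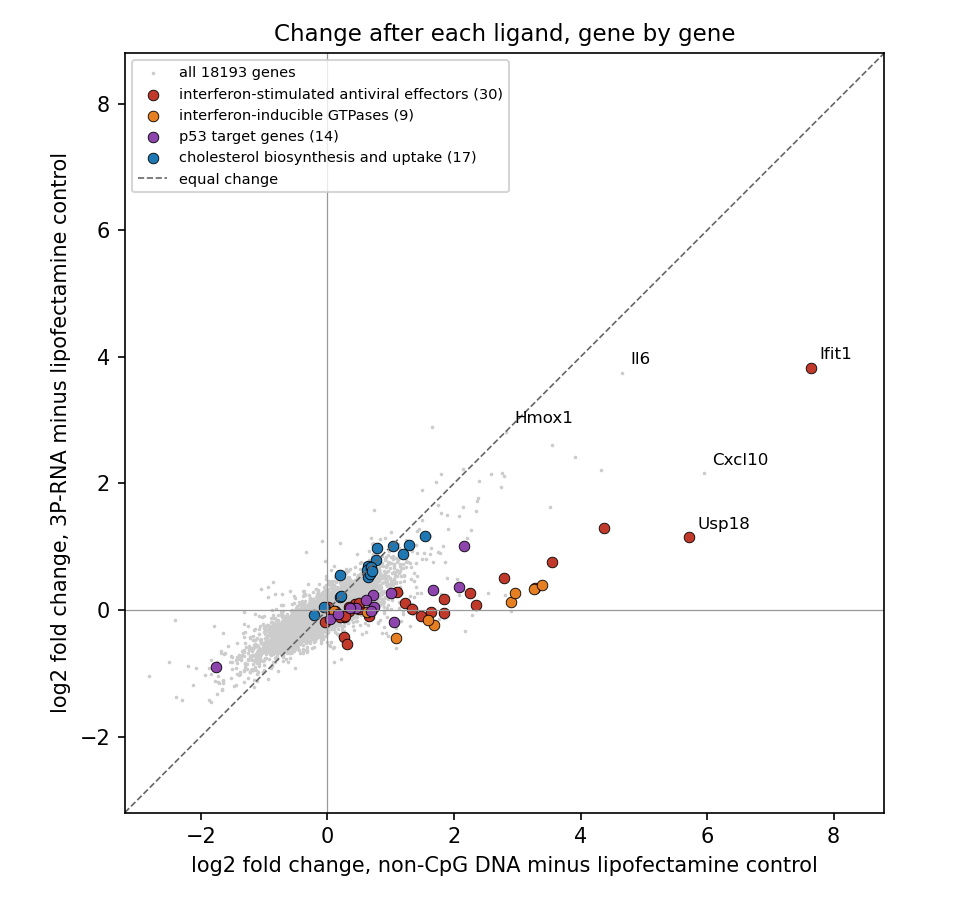
Log2 fold change after non-CpG DNA (x axis) against that after 3P-RNA (y axis), both against lipofectamine control, for 18193 genes (grey) and the members of 4 lists (colours); the dashed line marks equal change. Cholesterol genes lie near that line (medians 0.68 and 0.63), while most interferon-stimulated effectors lie under it (medians 0.88 and 0.03).

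The third comparison set 3P-RNA against non-CpG DNA directly. Most interferon-stimulated effectors, interferon-inducible GTPases and p53 target genes were lower after 3P-RNA, while cholesterol genes were not shifted as a list. Usp18 was 23.6-fold lower, Ifit1 14.0-fold and Cxcl10 13.9-fold. In the other direction Rgs4 was higher after 3P-RNA by 2.26 ± 0.07, or 1.89 with low values set to the overall median. The growth factor receptor Pdgfra was higher by 1.37 ± 0.07. In all, 1381 genes (7.59%) were called, 783 higher and 598 lower after 3P-RNA, and at a change of at least 2-fold 23 were higher and 74 lower.

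Of 30 interferon-stimulated effectors 20 were lower after 3P-RNA and 0 higher (27 and 0 adjusted over the list alone), with a median of -0.83 (camera adjusted p = 5.2e-34, and 0.00791 with an estimated correlation). Rtp4 was lower by 3.06 ± 0.15, Ifit3 by 2.94 ± 0.12 and Rsad2 by 2.78 ± 0.18. GTPases were lower in 7 of 9 (8 adjusted over the list alone; median -1.91, camera adjusted p = 5.35e-18, and 0.0199 with an estimated correlation), with Gbp3 at -2.93 ± 0.09, Irgm2 at -2.78 ± 0.11 and Igtp at -2.70 ± 0.09. The p53 targets were lower in 11 and higher in 1 of 14 (13 and 1 adjusted over the list alone; median -0.58, camera adjusted p = 8.69e-14, and 0.0146 with an estimated correlation). Mdm2 was at -1.73 ± 0.07, Cdkn1a at -1.36 ± 0.09, Trp53inp1 at -1.24 ± 0.11 and Btg2 at -1.15 ± 0.15. Cell death genes were lower in 8 and higher in 1 of 22 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000101, and 0.0407 with an estimated correlation), with Xaf1 at -2.93 ± 0.17 and Pmaip1 at -1.84 ± 0.08.

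In 8 further lists the camera call held with the preset correlation and was lost with an estimated one. Immediate-early genes were lower in 11 of 17 (12 adjusted over the list alone; median -0.56, adjusted p = 0.0768 with an estimated correlation), with Fosl1 at -1.07 ± 0.10 and Fos at -1.01 ± 0.14. Inflammatory genes were lower in 11 and higher in 4 of 34 (13 and 4 adjusted over the list alone; median -0.13, adjusted p = 0.0768 with an estimated correlation). Csf2 was lower by 0.89 ± 0.10, Il1rn was higher by 1.25 ± 0.08, and Il6 was lower by 0.91 ± 0.23, a call lost in 11 alternatives that included leaving out single arrays. Interferon receptor signalling was lower in 6 of 18 (8 lower and 2 higher adjusted over the list alone; adjusted p = 0.0654 with an estimated correlation), with Irf7 at -2.26 ± 0.21, Stat2 at -1.65 ± 0.15 and Irf9 at -1.57 ± 0.09. Sensors were lower in 6 of 20, also adjusted over the list alone (adjusted p = 0.0597 with an estimated correlation), with Ifih1 at -2.56 ± 0.12 and Trim25 at -1.14 ± 0.10. Genes of the MHC class I list were lower in 5 of 15 (8 adjusted over the list alone; adjusted p = 0.0654 with an estimated correlation), with Tap1 at -1.68 ± 0.10. Cd274, counted in the list though no MHC class I gene, was at -1.24 ± 0.14. Chemokines were lower in 6 and higher in 1 of 27 (7 and 3 adjusted over the list alone; camera adjusted p = 0.0435, adjusted p = 0.135 with an estimated correlation, and lost with a second quantile normalization, array weights, other choices of probe set, and without non-CpG DNA replicate 1 or 2 or 3P-RNA replicate 3). Ccl5 was at -2.10 ± 0.11 and Cxcl12 at 0.96 ± 0.12. Cell cycle genes were higher in 8 of 24 (15 adjusted over the list alone; median 0.25, adjusted p = 0.132 with an estimated correlation), with Mcm4, a subunit of the replicative helicase, at 0.48 ± 0.07 and Ccnb2 at 0.47 ± 0.09. Matrix genes were higher in 3 of 29, also adjusted over the list alone (median 0.12, adjusted p = 0.181 with an estimated correlation), with Lama4 at 0.47 ± 0.07.

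Cholesterol genes had 0 higher and 2 lower of 17, also adjusted over the list alone (median 0.00, camera adjusted p = 0.605). Those were Msmo1 at -0.32 ± 0.08 and Idi1 at -0.27 ± 0.07, and both calls were lost without any 1 of the 3P-RNA arrays. The stress response list was not shifted (median -0.02, camera adjusted p = 0.52), although Atf3 was lower by 1.89 ± 0.16 and Chac1 higher by 0.70 ± 0.08. List medians and camera adjusted p were 0.00 and 0.806 for mesangial markers, -0.01 and 0.714 for macrophages and leukocytes, -0.03 and 0.576 for lymphocytes, -0.02 and 0.528 for endothelium, 0.06 and 0.576 for podocytes, 0.00 and 0.739 for tubular epithelium, -0.08 and 0.118 for MHC class II, -0.05 and 0.543 for interferon genes, and 0.03 and 0.576 for reference genes. Among these, fry called the mesangial list upward (adjusted p = 0.0441). The macrophage list had a mean of 0.01, against the sign of its median and its test. Of the interferon genes limma called 0, with 0 at an unadjusted p under 0.05. Synpo was higher by 0.71 ± 0.08 and Edn1 lower by 0.72 ± 0.08.

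Other genes higher after 3P-RNA than after non-CpG DNA were Dhrs3 by 1.78 ± 0.19, the retinoic acid receptor Rarb by 1.54 ± 0.22, Lrrc17 by 1.32 ± 0.13, the prostaglandin receptor Ptgfr by 1.31 ± 0.10, Lgr5 by 1.31 ± 0.15, Prickle1 by 1.29 ± 0.07 and Rnf144a by 1.28 ± 0.07. Of the 752 genes higher after both ligands 164 differed between them, 158 stronger after non-CpG DNA and 6 after 3P-RNA. Of the 1450 lower after both 343 differed, 341 stronger after non-CpG DNA and 2 after 3P-RNA. Those 2, named after their values were seen, were Ndrg1 and Pink1, and Dio2, Olr1 and Vcam1 were among the 6. Counts of this comparison also rested on single arrays, with 385 genes higher without 3P-RNA replicate 3, 394 without 3P-RNA replicate 2, and 505 without non-CpG DNA replicate 3, and with 378 lower without 3P-RNA replicate 2.

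**Figure D3:**
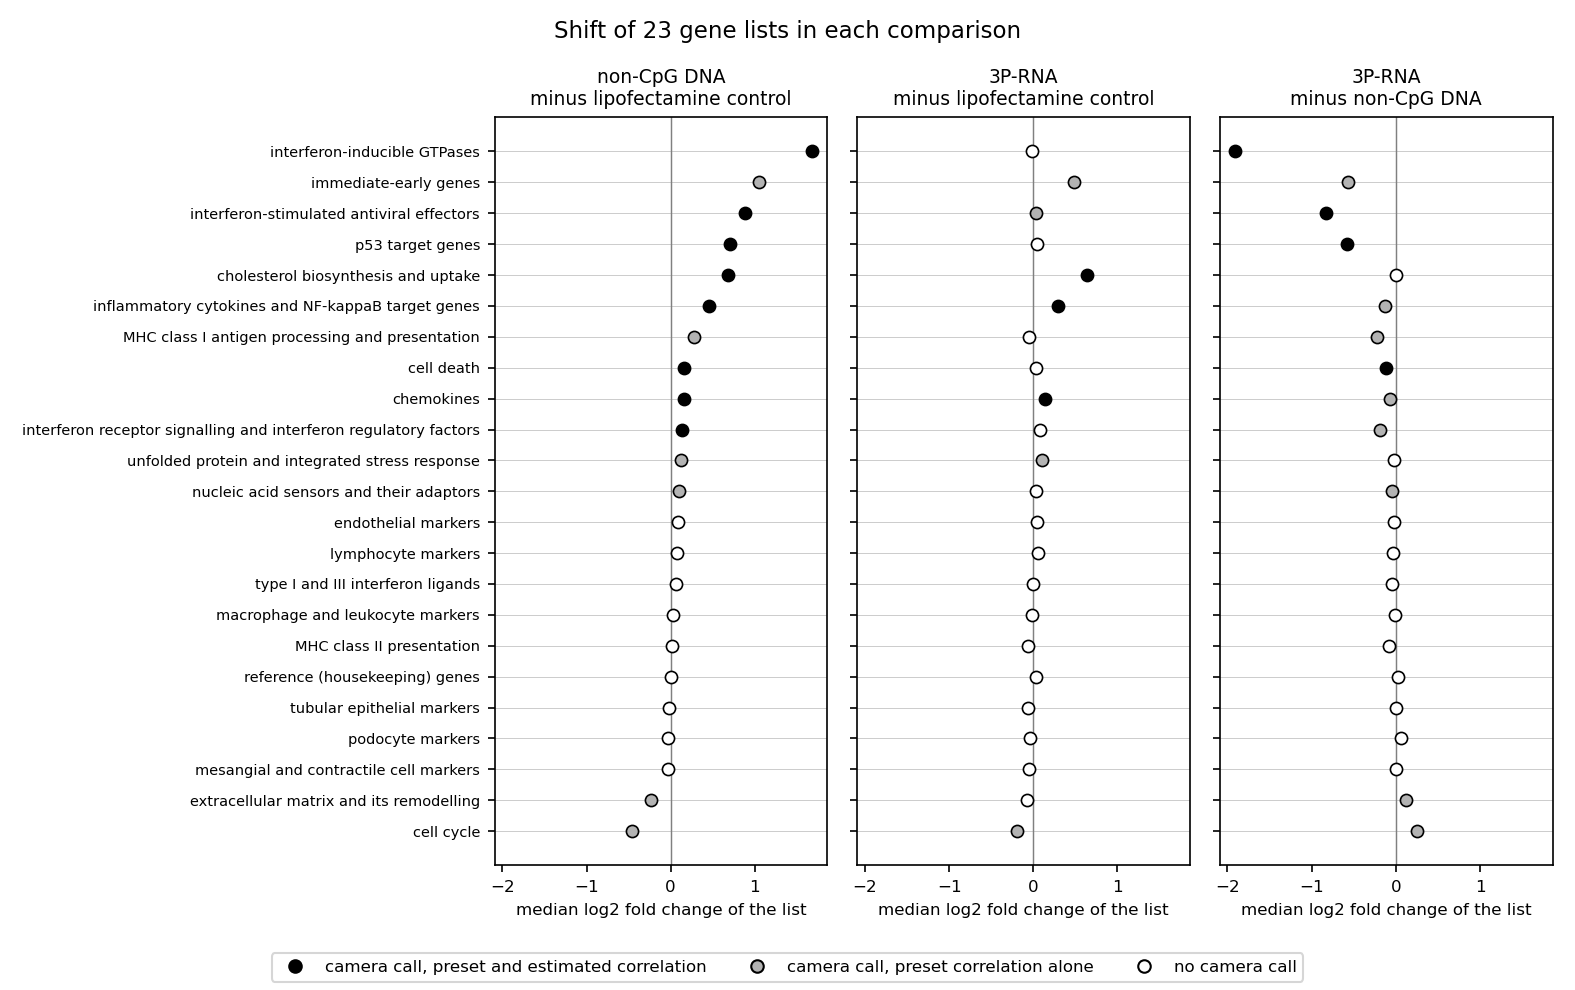
Median log2 fold change (x axis) of 23 gene lists (rows) in the 3 comparisons, with filled points for camera calls that held with an estimated correlation, grey points for calls at the preset correlation alone and open points for no call. After non-CpG DNA 8 lists kept their call with an estimated correlation, after 3P-RNA 3, and between the ligands 4.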

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

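In this part the tests of a single scaling factor, of normalization, of a mixed control sample and of other splits of the arrays were chosen after the results were seen. No test of the gap between 1 array and the others of its group was run on groups of 3, and single arrays were assessed by array weights over all 9 arrays.

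Probe sets that carry no gene name here stood outside the comparisons. Of 9160 such probe sets, 667 were called by limma after non-CpG DNA and 179 after 3P-RNA. Above the level in the controls by at least 2-fold were 19 after non-CpG DNA, with a largest rise of 5.75, and 6 after 3P-RNA, with a largest rise of 3.57. Which transcripts they read was not analysed here.

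The interferon-stimulated effectors rose less after 3P-RNA than after non-CpG DNA (difference of the list median -0.83), while the cholesterol genes did not differ as a list. If 1 linear factor scaled the whole 3P-RNA response, both lists would show the same ratio of responses. The ratio was 0.867 to 1.03 over the 3P-RNA arrays for cholesterol genes and -0.0344 to 0.136 for effectors, a gap of 0.7311, which argues against such a factor. Normalization acting by intensity would move other genes of like intensity as well. Yet the lowest median of 10000 random lists matched on mean expression over all 9 arrays was -0.1274. That mean includes the rise of the effectors, so matched genes need not share their intensity on any 1 array. Only a shift by mean intensity is therefore covered. A different reaction to the ligand may remain, as may differences in dose, uptake or timing that act unequally on the lists, none of which was tested.

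Control replicate 1 stood apart from the other controls, with a Hmox1 level of 4.74 against 6.12 and 6.46 and the lowest array weight of the controls, 0.509, although non-CpG DNA replicates 1 and 2 had weights nearly as low (0.527 and 0.593). A partial response to a ligand would move it toward the ligand arrays on the first principal component, but it lay at -26.57, the control farthest from them. Its log2 difference between 3′ and 5′ control probe sets, averaged over Gapdh and beta-actin, was 0.4584, the highest of the 9 arrays, with the next at 0.404. That rank rested on Gapdh (0.3732), since for beta-actin non-CpG DNA replicate 2 lay higher (0.5542 against 0.5436). Degraded RNA on that array may contribute, although the margin is small, beta-actin does not set the array apart, and no biological explanation was tested.

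Log2 fold changes after the ligands varied together, with a covariance of 0.0685. Shared controls could produce this, yet with different control arrays for each ligand the covariance was 0.06127 to 0.06486, so they are not the whole cause. A reaction common to the ligands may remain, as may an effect of how nucleic acid was delivered, since no group received an inert nucleic acid.

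Other splits of the arrays gave fewer genes. For each comparison of 3 against 3 arrays there are 10 splits, too few for a share under 0.05, and the real split alone (1 of 10) reached its own value for each count of genes and lists. The real counts of genes higher and lower were 2074 and 3215 after non-CpG DNA, 841 and 1624 after 3P-RNA, and 783 and 598 between the ligands, and the highest of the other splits was 0 by limma in each case. At an unadjusted p under 0.05 the real splits gave 6995, 4733 and 3757 genes and the highest others 1095, 824 and 1059. Each other split puts arrays of different groups together, so differences between the real groups widen the spread within a split group and lower its counts. The size of the gap to the other splits is therefore no measure of chance. Lists shifted by camera were 14, 7 and 12, against 10, 6 and 7 in the highest other split. For genes higher after both ligands (752) and lower after both (1450), 1 of 100 drawn splits of the 9 arrays, the real one, gave as many, the smallest share that 100 draws can give. That rank argues against a chance assignment of these arrays to the groups at that share. It says nothing about chance between cultures, since the arrays may not be separate cultures. The highest others, 577 and 1108, came from a split that kept the control arrays together and mixed the ligand arrays. There too, differences between the ligands widen the spread within a group.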

How the results depend on the processing

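The alternative with low values at the median was chosen after the data were seen. Of 5203 checks on 237 called values of named genes, 4768 stayed called in the same direction, 435 lost the call and 0 reversed. Of 726 checks on 33 called lists, 685 stayed and 41 lost the call, and 13 of 786 checks on 36 lists without a call gained one. With all probe sets tested, which tests more features, there were 3590 higher and 4942 lower after non-CpG DNA, 1297 higher after 3P-RNA and 1152 higher after both. At an adjusted p under 0.01, a stricter threshold, there were 1302 higher after non-CpG DNA, 401 higher and 695 lower after 3P-RNA, 318 and 329 between the ligands, and 360 higher and 652 lower after both. With a change of at least 2-fold required as well, there were 180 and 189, 58 and 31, 23 and 74, and 48 and 30. The share of called genes that were higher was 39.2%, 34.1% and 56.7% in the 3 comparisons, and 48.8%, 65.2% and 23.7% at 2-fold. With an estimated correlation 8, 3 and 4 lists were shifted, against 14, 7 and 12. Lists that lost their call after non-CpG DNA had estimated correlations of -0.0188 (sensors) to 0.426 (immediate-early genes), against the preset 0.01. For the sensors, whose estimated correlation lay under the preset, camera's unadjusted p after non-CpG DNA still rose from 0.0181 to 0.0419. For the chemokines, with an estimated correlation of 0.0109, it rose from 3.03e-05 to 0.0061. These values argue against a higher correlation as the cause of weaker p-values in those lists. How far correlation accounts for the calls lost in the others was not tested. Fry called 19, 8 and 13. Leaving out 1 array, which leaves 2 in its group, gave 1713 to 2027 higher and 2678 to 3204 lower after non-CpG DNA, and 431 to 899 and 745 to 1799 after 3P-RNA, lowest without 3P-RNA replicate 1. Between the ligands it gave 385 to 853 higher, lowest without 3P-RNA replicate 3, and 378 to 645 lower, lowest without 3P-RNA replicate 2. It gave 399 to 766 higher after both ligands and 689 to 1599 lower after both, each lowest without 3P-RNA replicate 1, with 488 higher without 3P-RNA replicate 3 and 925 lower without control replicate 3. Lists shifted were 13 to 14, 6 to 7 and 11 to 13. The design fixed beforehand did not take the replicate numbers as pairs. Residuals of arrays with the same number correlated at -0.139 to 0.152, and those with different numbers at -0.1999 to 0.1926. Between control and ligand arrays alone, they were 0.007 to 0.152 with the same number and -0.136 to 0.050 with different numbers. These ranges overlap and do not settle whether the arrays were paired, although the former lean toward higher values. With the replicate number as a replicate block there were 2036 and 3184, 820 and 1512, 728 and 581 genes higher and lower in the 3 comparisons, 729 and 1362 after both ligands, and 13, 7 and 12 lists. Signal over background limits values under the overall median, where folds of genes such as Usp18 after 3P-RNA depend on how low values are read.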

Other observations

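The lists in this part were chosen after the values were seen, and the tests on them leave out the genes that prompted them. Their camera p-values are adjusted over 12 tests.

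Hmox1, a target of the oxidative stress factor NRF2, was among the largest rises after 3P-RNA, and rose by 2.83 ± 0.43 after non-CpG DNA as well. Of 12 other measured NRF2 targets 9 rose after 3P-RNA and 0 fell, with a median of 0.4855 (camera adjusted p = 3.28e-10, and adjusted p = 0.0614 with an estimated correlation). After non-CpG DNA 10 of the 12 rose, with a median of 0.89 (camera adjusted p = 4.66e-09, and adjusted p = 0.0614 with an estimated correlation). The antioxidant genes Srxn1 and Gclm rose by 1.17 and 0.95 after 3P-RNA and by 1.61 and 1.22 after non-CpG DNA, and Nqo1 by 0.74 and 1.39. The list was lower after 3P-RNA than after non-CpG DNA, with 4 members lower and a median of -0.25. Its camera adjusted p was 2.83e-05, lost at adjusted p = 0.108 with an estimated correlation. Hmox1 itself rose by 2.82 after 3P-RNA and 2.83 after non-CpG DNA. A rise of NRF2 targets as a group may underlie the change in Hmox1, a hypothesis that stays open because the call was lost with the estimated correlation. The rise of Hmox1 after 3P-RNA was 2.30 without control replicate 1 (limma adjusted p = 0.00418, with a range of 0.000501 to 0.0251 over the alternatives).

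Nr4a2 and Dio2, which respond to cyclic AMP, were among the largest rises after 3P-RNA. Of 10 other genes listed as targets of the cyclic AMP factor CREB 4 rose and 0 fell, with a median of 0.3278 (camera adjusted p = 0.00115, and adjusted p = 0.0723 with an estimated correlation). The phosphodiesterase Pde4b rose by 1.66 and Crem by 1.42. After non-CpG DNA 5 of the 10 rose and 1 fell (median 0.33, camera adjusted p = 0.031, and adjusted p = 0.156 with an estimated correlation), with Pde4b up by 1.75, and Crem rose too. The 1 that fell was Crtc1 (-0.36), a coactivator of CREB rather than a target. The list was not called between the ligands (camera adjusted p = 0.855). A CREB response may be part of the change after either ligand, which the median of 0.3278 leaves open. Dbp fell after both ligands. Of the other clock and clock output genes 3 rose and 5 fell after non-CpG DNA, with a median of -0.08432 (camera adjusted p = 0.536). After 3P-RNA 3 rose and 4 fell, with a median of -0.07 (camera adjusted p = 0.536). A list median cannot show a change in which members move in opposite directions. Among those that fell after non-CpG DNA were Per2, Per3 and Tef (-1.22, -1.15 and -0.51). The 3 that rose were Bhlhe40, Cry1 and Arntl (0.68, 0.58 and 0.51). After 3P-RNA Per3 and Tef were at -0.80 and -0.60, and Arntl at 0.345. A change of the clock was therefore left open. Ereg rose after both ligands. Of 7 other genes listed as EGF receptor ligands 6 were measured, among them Nrg1, a ligand of related receptors rather than of the EGF receptor. Of the 6 measured 2 rose after non-CpG DNA, Hbegf by 1.16 and Btc by 0.96, with a list median of 0.1187 (camera adjusted p = 0.0404, and adjusted p = 0.16 with an estimated correlation). After 3P-RNA 1 of the 6 rose, Hbegf by 0.54, and the list was not called (median 0.08, camera adjusted p = 0.183). It was lower after 3P-RNA than after non-CpG DNA (camera adjusted p = 0.0325, lost at adjusted p = 0.158 with an estimated correlation). A rise of the family was not settled.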
